A study of Citrullus lanatus with 26 samples.

How the data were processed

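Small RNA was measured in the fruit flesh of watermelon (Citrullus lanatus) in 26 libraries. The labels give each library a genotype, either the cultivar 97103 or the germplasm accession PI296341FR, and a fruit age in DAP, the unit the labels use. The first set, called the stage set here, holds 18 libraries of 97103 at 0, 1, 5, 10, 20 and 30 DAP with 3 replicates each. The second set, called the genotype set here, holds 8 libraries of 97103 and PI296341FR at 10 and 30 DAP with 2 replicates each. Groups and replicate numbers were taken from the titles. The labels do not say whether replicates came from separate plants, so the p-values measure only the spread between these libraries, which may be technical.

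Per the labels' protocols, flesh RNA was extracted with Trizol, the fraction below 100 nt was purified from a gel, and small RNA libraries were sequenced on an Illumina instrument. The submitters' processing notes name fastp and BWA without a role or a version. The genome build, the miRNA reference and the counting rule are not given in the sources used here. Each deposited table holds whole-number counts per miRNA name for 1 library, and the values carry no normalization. No reference genome was used here, so no position or sequence is given for any name, and the names are printed as the tables write them. Names starting with novel_miR in the stage set, and with novel_mir in the genotype set, come with no sequence, and the same number in both sets was not taken as the same molecule.

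The stage set lists 208 names, of which 179 are novel_miR names and 29 carry a species prefix and a family number, such as cme-miR159a. Its listed totals run from 62050 to 153755 counts per library. The genotype set lists 1263 names, with totals from 991234 to 60765998. Most of its names are members of known families taken from many plant species, and the 1263 names hold only 426 different patterns of counts. The sources used here do not say how a read that matches several names was counted. Where names share their counts, a total over names is not a number of reads, and members of a family are read here as copies of each other. Names of a family whose counts lay within 0.1 of each other in every library, on the log2 scale of count plus 1, were joined into 138 profiles, and with 1 name per profile the totals run from 66572 to 1426662. Each of the 1263 names has at least 1 count in all 8 libraries, so a molecule missing from a library is not analysed here. Intervals and floors cover counting error only, since the labels mention no molecular identifiers.

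Counts were analysed with edgeR 4.0.16 in R 4.3.3. Low names were removed with filterByExpr at its minimum count of 10, libraries were scaled with trimmed-mean (TMM) factors, and group means were compared with the quasi-likelihood F test, each set in its own fit with no other term. Benjamini-Hochberg adjusted p-values under 0.05 were called within each comparison. This left 204 names in the stage set and 1261 in the genotype set. The stage comparisons were an F test over all ages, 30 against 0 DAP, and each step between neighbouring ages. The genotype comparisons were 30 against 10 DAP in each genotype, PI296341FR against 97103 at each age, and the interaction of genotype and age. A test of set by age was the exception to separate fits. It joined the 97103 libraries of both sets at 10 and 30 DAP over their 18 shared names, without the filter. Abundances are TMM-scaled CPM with the SD over replicates. Where a group had no count, a change is given as a lower bound against a floor of 3 counts over the pooled group. Where it had 1 to 3 counts, the ratio of scaled counts is given with an exact 95% counting interval. The common dispersion was 0.0323 in the stage set and 0.422 in the genotype set. Spearman correlations between replicates of a group lay between 0.948 and 0.995 in the stage set and between 0.910 and 0.960 in the genotype set, and no replicate pair differed by less than sampling noise.

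Lists of miRNA families were fixed by family number from textbook targets: phase change (miR156, miR157, miR172), auxin (miR160, miR167, miR390, miR393), organ growth and meristem (miR164, miR165, miR166, miR171, miR319, miR396), MYB regulators (miR159, miR828, miR858), copper (miR397, miR398, miR408, miR857), phosphate and sulphate (miR395, miR399, miR827, miR2111), miRNA pathway (miR162, miR168, miR403), NBS-LRR defence (miR472, miR482, miR1507, miR2109, miR2118, miR5300), ripening regulators (miR156, miR157, miR164, miR172, miR1917) and phloem-mobile families as markers of another tissue (miR395, miR398, miR399, miR827, miR2111). Lists with 3 or more tested names were tested with fry (limma 3.58.1). Its directional p tests whether the names of a list move, on balance, one way, and its mixed p whether they change in either direction. In the stage set both p-values were adjusted over the lists in the comparison of the oldest with the youngest flesh. In the genotype set they were adjusted over the lists and the comparisons of genotype groups. The fry p-values of the steps between ages and of the interaction were not adjusted and are not reported.

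Names in the text follow a rule: the 8 largest rises and falls among called names without overlap between groups for 30 against 0 DAP and for the 4 comparisons of genotype groups, the 3 largest rises and falls in each step and in the interaction, the 5 most abundant names of each set, and the 2 most abundant tested members of each list. The groups, tests, lists, naming rule and the first group of other settings below were chosen before the data were examined. Other names, among them those of the table of families and those called with pairing at 0 and 1 DAP, were chosen after their values were seen.

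The other settings were, first, DESeq2 1.42.0, median-of-ratios (RLE) factors in edgeR, no scaling factors, no filter, a mean count of at least 50, the replicate number as a block, counts summed per family, only the groups compared in the fit, a change of at least 1 on the log2 scale, and leaving out replicates in turn. Added after seeing the data were 1 name per profile, single libraries left out of the stage set, a block over the 0 and 1 DAP libraries alone, crossed replicate numbers at 30 DAP, and RLE factors for the lists and for the comparison of the sets. Replicate numbers are shared between groups by the titles alone. Deviations from the group mean correlated between libraries of the same number at 0 and 1 DAP (r = 0.29, 0.81 and 0.66 across names), so the numbers were taken as pairs there. In every other step, and between 0 and 30 DAP, at least 1 of the 3 correlations was under 0.1.

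The tests were run first on simulated counts drawn with the means and library sizes of these data. In a simulation of 30 against 0 DAP with 202 names, 40 of them changed, edgeR recovered 71.4% of 2-fold, 100% of 4-fold and 100% of 16-fold changes, and 2.70% of its calls were false. In a simulation of PI296341FR against 97103 at 30 DAP with 1258 names, 200 of them changed, it recovered 3.03% of 2-fold, 12.1% of 4-fold and 67.2% of 16-fold changes, and 1.79% of its calls were false. The 16-fold size was added after the low recovery in the genotype set was seen. In this simulation, at 2 libraries per group, mainly large differences were detected. Both simulations drew each name independently and changed about as many names up as down. The genotype set holds many names that share counts, and its median moves with the scaling, so the recovered and false shares do not carry over to it.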

Results

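The series measured small RNA in watermelon flesh, and its design text describes 6 fruit ages of the cultivar 97103 in triplicate. A further set of libraries compares 97103 with the germplasm accession PI296341FR at 10 and 30 DAP. Total counts per library were 62050 to 153755 in the stage set. In the genotype set they were 991234 to 60765998 over all listed names and 66572 to 1426662 with 1 name per profile. cme-miR159a, of the miR159 family that targets GAMYB-type transcription factors, was the most abundant name in all 12 stage libraries up to 10 DAP, and took 10.5% to 23.5% of their counts. At 20 and 30 DAP novel_miR_121 or novel_miR_30, whose counts are nearly identical, was the most abundant, with 10.4% to 16.1%.

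Which miRNAs differed between the youngest and the oldest flesh was asked with 30 against 0 DAP in the stage set. Flesh at 30 DAP had far more cme-miR319c, of the family that targets TCP transcription factors, at 96938 ± 11835 CPM against 7546 ± 1808 at 0 DAP (SD, n = 3 each). cme-miR164c, whose family targets NAC transcription factors, stood at 16539 ± 4548 against 1930 ± 511 CPM. Most of the largest changes lay among novel_miR names, which are 179 of the 208 listed. novel_miR_101 rose from 9.29 ± 8.14 to 15376 ± 4139 CPM, and novel_miR_15 fell from 21676 ± 2386 CPM to no count in the 3 libraries at 30 DAP. hbr-miR6485, which carries a family number, also rose steeply, by 9.03 on the log2 scale, from 2 counts at 0 DAP. The miR160 and miR167 names, which target auxin response factors, and the miR171 names, which target GRAS transcription factors, were lower at 30 DAP. Over the whole course novel_miR_121 rose from 12482 ± 1949 to 236549 ± 31551 CPM.

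By edgeR's quasi-likelihood test 138 of 204 names differed between 30 and 0 DAP, 58 higher and 80 lower, and 175 differed at some age. Without scaling factors the split was 31 higher and 135 lower, because the median of all names then moved from -0.01 to -1.06 on the log2 scale. Changes without factors therefore lie lower than those with TMM factors by about that amount. TMM factors take most names as unchanged, but most were called here. The factors were 1.24 to 1.39 at 0 DAP and 0.53 to 0.70 at 30 DAP. Which scaling lies nearer to the true change is not known, so the split and the sizes rest on this choice.

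Among the rises, novel_miR_101 had a log2 fold change of 10.56 (SE 0.43) with an edgeR adjusted p of 5.66e-13. novel_miR_40 rose by 7.94 (SE 0.42), and novel_miR_14 and novel_miR_60, which have the same counts in every library, by 7.35 (SE 0.34). novel_miR_146 and novel_miR_175, also identical to each other, rose by 6.99 (SE 0.34), and novel_miR_99 by 6.11 (SE 0.36). hbr-miR6485 had 2 counts over the libraries at 0 DAP and 484 at 30 DAP, a ratio of 645 with a counting interval of 178 to 5344. The most abundant names, novel_miR_30 and novel_miR_121, rose by 4.28 and 4.24.

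Among the falls, novel_miR_15 had 9440 counts at 0 DAP and none at 30 DAP, at least 1180-fold lower. novel_miR_13 had 814 and none, at least 102-fold lower. novel_miR_51 had 6971 counts at 0 DAP and 1 at 30 DAP, a ratio of 2614 with an interval of 469 to 103261. The ratios of novel_miR_100, novel_miR_19, novel_miR_165 and novel_miR_27, each with 1 count at 30 DAP, were 955, 943, 932 and 924, and that of novel_miR_109 was 444 (interval 79.5 to 17536). The edgeR adjusted p-values of these novel_miR falls ran from 3.04e-12 for novel_miR_15 to 9.74e-10 for novel_miR_109. Each name was lower in all 3 libraries at 30 DAP than in any at 0 DAP, which the naming rule required and which is no added support.

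Of the 25 tested names of known families, 6 were higher at 30 DAP, 9 were lower and 10 were not called. The auxin list had 4 tested names, all lower, and 4 were lower adjusted over the list alone (fry, down, adjusted p = 0.000386). cme-miR160a and cme-miR160c fell by 3.67 (SE 0.62) and 3.68 (SE 0.60) on the log2 scale, and cme-miR167b and cme-miR167c fell by 1.28 (SE 0.40) and 1.57 (SE 0.40). The organ growth and meristem list had 9 tested names, 3 higher and 4 lower, with the same numbers adjusted over the list alone. Its members moved in both directions (fry mixed, adjusted p = 4.86e-08), and the directional fry test did not pass (adjusted p = 0.463). cme-miR319c rose by 3.68 (SE 0.30), cme-miR164c by 3.10 (SE 0.31) and cme-miR319a by 1.24 (SE 0.24). Without scaling factors 2 were higher and 6 lower: cme-miR319a was not called, at 0.17, and cme-miR166b and cme-miR319b, not called at -0.16 and 0.55 with TMM factors, were called lower at -1.26 and -0.52. The directional fry test then passed, down, with an adjusted p of 0.0187. cme-miR171a had 484 counts at 0 DAP and 3 at 30 DAP, a ratio of 60.5 with an interval of 20.6 to 294. cme-miR171c and mdm-miR171h had none at 30 DAP, at least 6.62-fold and 5.62-fold lower, and cme-miR171d had 1 against 51, a ratio of 19.1 (interval 3.28 to 770.0).

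In the phase change list, cme-miR172b, whose family targets AP2-like transcription factors, fell by 1.28 (SE 0.35). The other 5 names, all of miR156, which targets SPL transcription factors, had changes of 0.55 to 0.76 that were not called. The list had 0 higher and 1 lower of 6, and the same adjusted over the list alone (fry, up, adjusted p = 0.463). Without scaling factors its fry test passed, down, with an adjusted p of 0.0424 and a list median of -0.46. The ripening regulator list shares these families and adds cme-miR164c. It had 1 higher and 1 lower of 7, the same adjusted over the list alone (fry adjusted p = 0.138, mixed adjusted p = 0.00775). The 2 MYB regulator names were not called (cme-miR159a 0.10, cme-miR159b 0.51), nor was the miRNA pathway name, cme-miR162 (0.24), whose family targets DCL1. Without scaling factors these 3 were called lower. cme-miR2111a, of a family induced by phosphate starvation, rose by 4.23 (SE 0.40), and it was the 1 tested name of both the phosphate and sulphate list and the phloem-mobile list. cme-miR530b rose by 2.64 (SE 0.36). No name of the copper or NBS-LRR defence lists was tested in the stage set, and none of the NBS-LRR list in the genotype set.

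**Figure D1:**
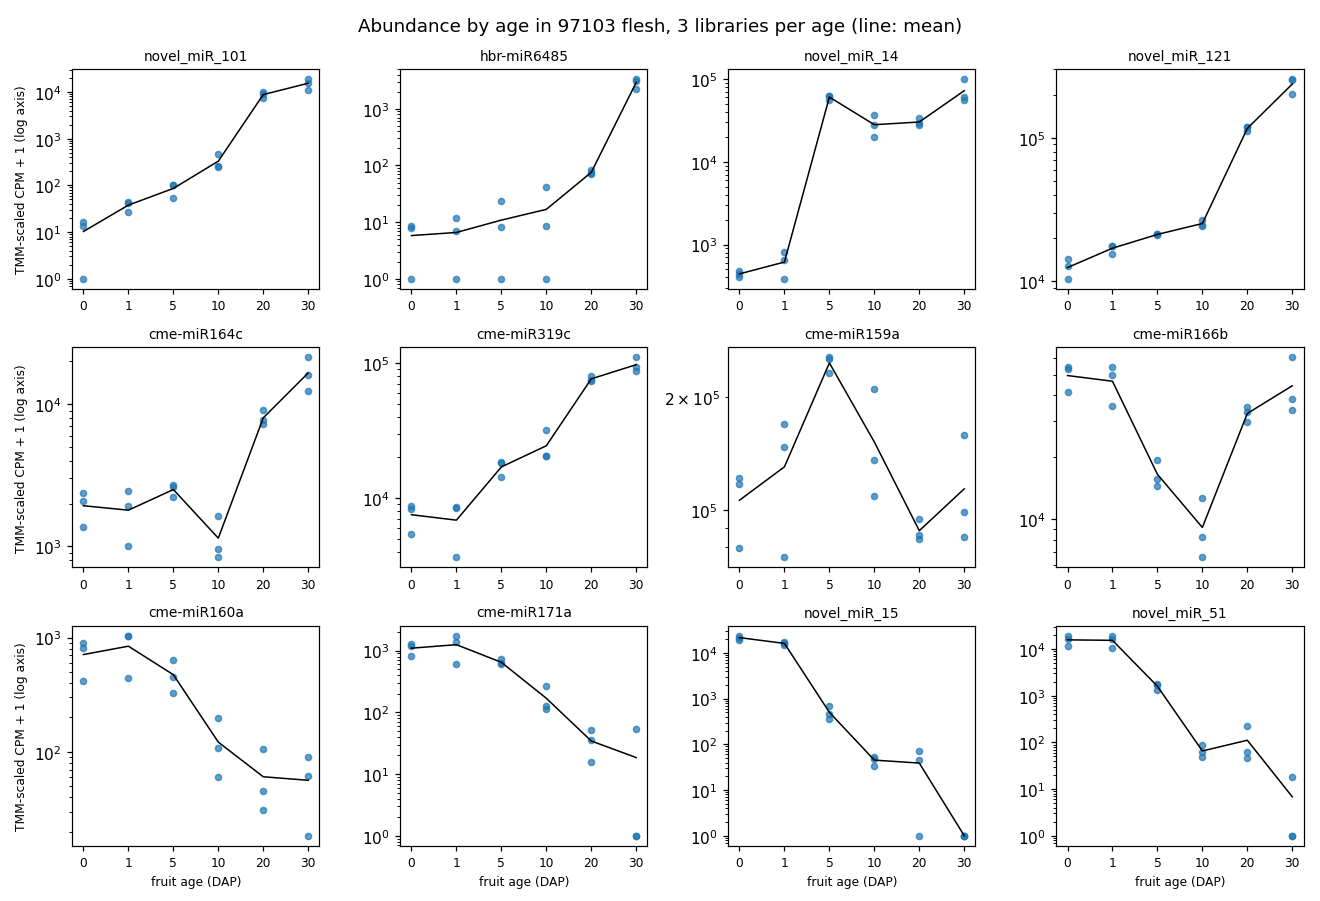
TMM-scaled abundance (CPM plus 1, log axis) of 12 names against fruit age in DAP in 97103 flesh, with a point for each of the 3 libraries per age and a line through the means. novel_miR_101 and hbr-miR6485 climb late, novel_miR_14 climbs between 1 and 5 DAP, novel_miR_15 and novel_miR_51 fall between 1 and 10 DAP, and cme-miR166b is lowest at 10 DAP with 9149 CPM.

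The steps between neighbouring ages show when these names moved. Between 0 and 1 DAP novel_miR_15 stood at 21676 ± 2386 and 16184 ± 1254 CPM, novel_miR_121 at 12482 ± 1949 and 17029 ± 1234 CPM, and cme-miR319c at 7546 ± 1808 and 6880 ± 2788 CPM (SD, n = 3). By edgeR's test 0 of 204 names were called, with 27 at an unadjusted p under 0.05 and a lowest adjusted p of 0.173, and DESeq2 called 3, all lower at 1 DAP. With replicate numbers as pairs, in a fit of these 6 libraries alone chosen after seeing the data, edgeR called 37, with 15 higher and 22 lower. Its largest changes were novel_miR_179 (1.13, SE 0.19), novel_miR_99 (0.82, SE 0.29), novel_miR_90 (-0.91, SE 0.19) and novel_miR_54 (-0.80, SE 0.16). cme-miR162 was the 1 name of a known family among the 37, at 0.37 (SE 0.10, adjusted p = 0.00249). novel_miR_30 and novel_miR_121 were at 0.49 and 0.47, and novel_miR_15 was at -0.40. The same block over all 18 libraries gave 0 calls.

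The step from 1 to 5 DAP held the most calls of any step. novel_miR_14 and novel_miR_60 rose by 6.63 (SE 0.33) on the log2 scale, novel_miR_14 from 613 ± 216 to 60558 ± 3707 CPM, and novel_miR_40 rose by 4.79 (SE 0.60). novel_miR_15 fell by 5.02 (SE 0.27), novel_miR_109 by 3.39 (SE 0.31) and novel_miR_51 by 3.27 (SE 0.29). cme-miR166b, of the family that targets class III HD-ZIP transcription factors, fell by 1.49 (SE 0.25), and cme-miR319c rose by 1.31 (SE 0.27). edgeR called 109 names, 56 higher and 53 lower. Without scaling factors the split was 39 and 96.

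From 5 to 10 DAP novel_miR_99 rose by 2.02 (SE 0.27), novel_miR_40 by 2.01 (SE 0.32) and novel_miR_101 by 1.93 (SE 0.36). novel_miR_51 fell by 4.61 (SE 0.38). novel_miR_13 had 105 counts at 5 DAP and 2 at 10 DAP, a ratio of 56.9 with an interval of 15.4 to 476, and novel_miR_109 had 126 and 3, a ratio of 45.5 with an interval of 15.2 to 224. cme-miR166b fell further, by 0.85 (SE 0.25), and cme-miR164c fell by 1.14. Calls numbered 79, with 23 higher and 56 lower, and without scaling factors 64 higher and 34 lower. They numbered 48 without replicate 2 of 5 DAP and 49 without replicate 2 of 10 DAP.

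From 10 to 20 DAP novel_miR_101 rose by 4.75 (SE 0.28), from 329 ± 126 to 8783 ± 1309 CPM, and cme-miR164c rose by 2.81 (SE 0.31), from 1142 ± 422 to 7996 ± 905 CPM. novel_miR_63 rose by 2.23 (SE 0.26), novel_miR_30 and novel_miR_121 by 2.22 and 2.20, cme-miR166b by 1.83 (SE 0.26) and cme-miR319c by 1.64 (SE 0.27). novel_miR_153 fell by 2.32 (SE 0.47) and novel_miR_87 by 2.30 (SE 0.47). cme-miR171a fell by 2.19 (SE 0.72, edgeR adjusted p = 0.0422), a call that RLE factors, no filter and the stricter filter each ended with adjusted p-values of 0.0534 to 0.0553. Calls numbered 40, with 19 higher and 21 lower. The split was 14 and 56 without scaling factors and 32 and 23 by DESeq2, and calls numbered 23 without replicate 2 of 10 DAP and 22 without replicate 3 of 20 DAP.

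From 20 to 30 DAP hbr-miR6485 rose by 5.26 (SE 0.40), from 74.6 ± 5.66 to 2928 ± 582 CPM. novel_miR_93 and novel_miR_2 rose by 2.39 and 2.38 (SE 0.30 each), and novel_miR_121 and novel_miR_30 by 1.03. novel_miR_51 had 22 counts at 20 DAP and 1 at 30 DAP, a ratio of 16.0 with an interval of 2.59 to 662. novel_miR_1 fell by 1.56 (SE 0.27), novel_miR_41 by 1.39 (SE 0.26) and cme-miR162 by 1.14. cme-miR164c rose by 1.05 and cme-miR159b by 1.07, and without scaling factors neither was called. Calls numbered 40, with 23 higher and 17 lower, and 93 without scaling factors, with 13 higher and 80 lower.

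**Figure D2:**
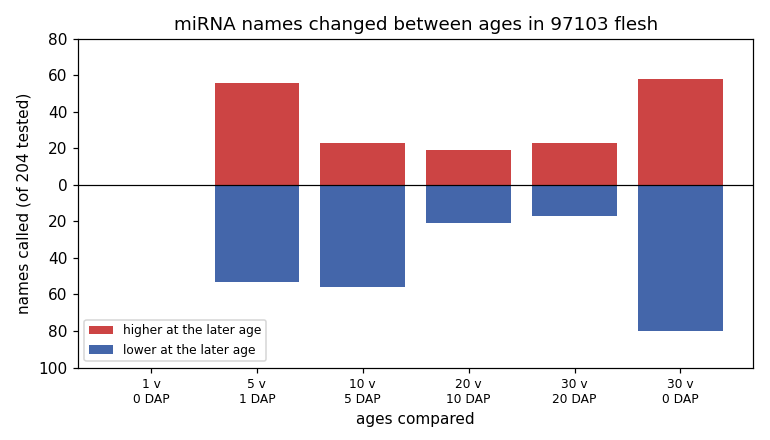
Number of names that edgeR called higher (above 0) or lower (below 0) at the later age in each step and for 30 against 0 DAP, of 204 tested in 97103 flesh. The step from 0 to 1 DAP has 0 calls, the step from 1 to 5 DAP has 56 higher and 53 lower, and 30 against 0 DAP has 58 higher and 80 lower.

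In the genotype set names of 9 families were called higher and names of 4 families lower in PI296341FR than in 97103 at 30 DAP, of 35 families tested. Of the copper list, all 20 names of miR408, which targets plantacyanin and laccases, were called higher in PI296341FR with a median log2 fold change of 7.23, and all 20 names of miR397, which targets laccases, with 3.87. These 40 names are 6 profiles, and the list as a group did not pass fry (up, adjusted p = 0.129, mixed adjusted p = 0.0934). All 46 names of miR390, which triggers trans-acting small RNAs against auxin response factors, had a median of 6.11, and 41 of 42 names of miR319 were higher, with a family median of 3.48. The names of miR165 and miR166, which target class III HD-ZIP transcription factors, were lower: 4 of 4 with a median of -4.94 and most of 201 with a median of -4.32. In counts over both libraries, cme-miR408 had 650 in PI296341FR and 20 in 97103 (log2 fold change 7.34, SE 1.60), and cme-miR166b had 3021 and 482693 (-5.26), both with an edgeR adjusted p of 0.00015.

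By edgeR's test 327 of 1261 names differed between the genotypes at 30 DAP, 133 higher and 194 lower in PI296341FR, which is 24 and 22 profiles. The median of all names was -0.03 with TMM factors, -0.56 with RLE factors and 1.70 without factors, and without factors the calls numbered 603 and split 480 higher and 123 lower. Relative to that median the values of a family lay close together under the 3 scalings: miR408 stood at 7.26 to 8.08, miR390 at 6.12 to 6.22, miR397 at 3.90 to 4.17 and miR319 at 3.32 to 3.51. miR165 stood at -4.90 to -4.73, and miR166 at -4.29 and -4.19 with TMM and RLE factors and somewhat nearer to 0 without factors. A change of factors moves all names of a comparison by nearly the same amount, and subtracting the median removes it. This closeness is therefore largely fixed in advance and is no support, here or in the other comparisons. All 127 called names of the 4 higher families were called under each scaling, while of miR166 101 to 174 names were called lower and, without factors, 24 higher. Without replicate 2 of PI296341FR at 30 DAP the calls numbered 199. With 1 name per profile, which removes the copies, 39 profiles were called, 22 higher and 17 lower, and with counts summed per family 4 families.

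The remaining calls at 30 DAP were few per family. smo-miR408 had the largest log2 fold change, 7.39 (SE 1.59), and the 8 largest rises were all miR408 names and the 8 largest falls all miR166 names. cme-miR167e and aqc-miR167, vvi-miR2950-5p (3.35, SE 1.07), gma-miR6300 (4.11, SE 1.25), novel_mir_105 (3.19, SE 1.11) and 1 name of miR396, which targets growth-regulating factors, were higher. In miR156 16 of 210 names were lower, and in miR157 2 of 12. cme-miR319c was the 1 miR319 name not called (-1.05, SE 0.93), and the miR319 names rest on few counts, as rco-miR319b had 91 in PI296341FR and 21 in 97103. rco-miR319b, the most abundant miR319 name of this set, stood at 0.454 CPM in 97103 at 30 DAP. In the stage set cme-miR319c stood at 96938 CPM in the same cultivar and age. Copies enter the totals of the genotype set, so the CPM are not on the same scale, and the cause of this gap was not tested.

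Over the lists at 30 DAP, 40 of 40 copper names were higher, and 40 adjusted over the list alone. Of the organ growth and meristem list, 42 of 413 were higher and 176 lower, and adjusted over the list alone 42 and 178 (fry mixed adjusted p = 0.0296, directional adjusted p = 0.351). Of the auxin list, 48 were higher, and 48 adjusted over the list alone, with fry's direction up and a list median of -0.78 (adjusted p = 0.751). Of the phase change list, 18 of 324 were lower, as were 18 of 400 in the ripening regulator list, with the same numbers adjusted over the lists alone. The MYB regulator, phosphate and sulphate, phloem-mobile and miRNA pathway lists had 0 calls by edgeR at 30 DAP, and 0 adjusted over the list alone. Without scaling factors, where the median of all names lay at 1.70, all 135 names of miR395, all 31 of miR162 and all 102 of miR172 were called higher. The organ growth and meristem list then had 105 higher and 105 lower, the phase change list 105 higher, the ripening regulator list 137, the miRNA pathway list 33 and the MYB regulator list 2. The auxin, phosphate and sulphate, and phloem-mobile lists then passed fry, up, each with an adjusted p of 0.0377 and with list medians of 1.03, 2.88 and 2.88.

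At 10 DAP the genotypes differed less in number of calls. peu-miR2911, of a family derived from ribosomal RNA, was the 1 name that edgeR called, with 23 counts in PI296341FR and 2 in 97103, a ratio of 35.2 with an interval of 8.69 to 308. The miR390 names lay 3.67 to 3.91 above the median of all names and miR408 2.61 to 2.64 above it over the 3 scalings. The miR390 names were called under RLE factors (45 of 46) and without factors (46), and not with TMM factors, where bdi-miR390a stood at 3.95 (SE 1.32, adjusted p = 0.0789). At an unadjusted p under 0.05 there were 120 names. Calls numbered 48 by DESeq2, 48 with RLE factors, 50 without factors, 51 with the compared groups alone in the fit, 48 without replicate 1 and 0 without replicate 2 of 97103 at 10 DAP, and 0 without replicate 1 and 50 without replicate 2 of 97103 at 30 DAP. With 1 name per profile none was called. In the auxin list 46 names were higher adjusted over the list alone, all other lists had 0, and no list passed fry.

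**Figure D3:**
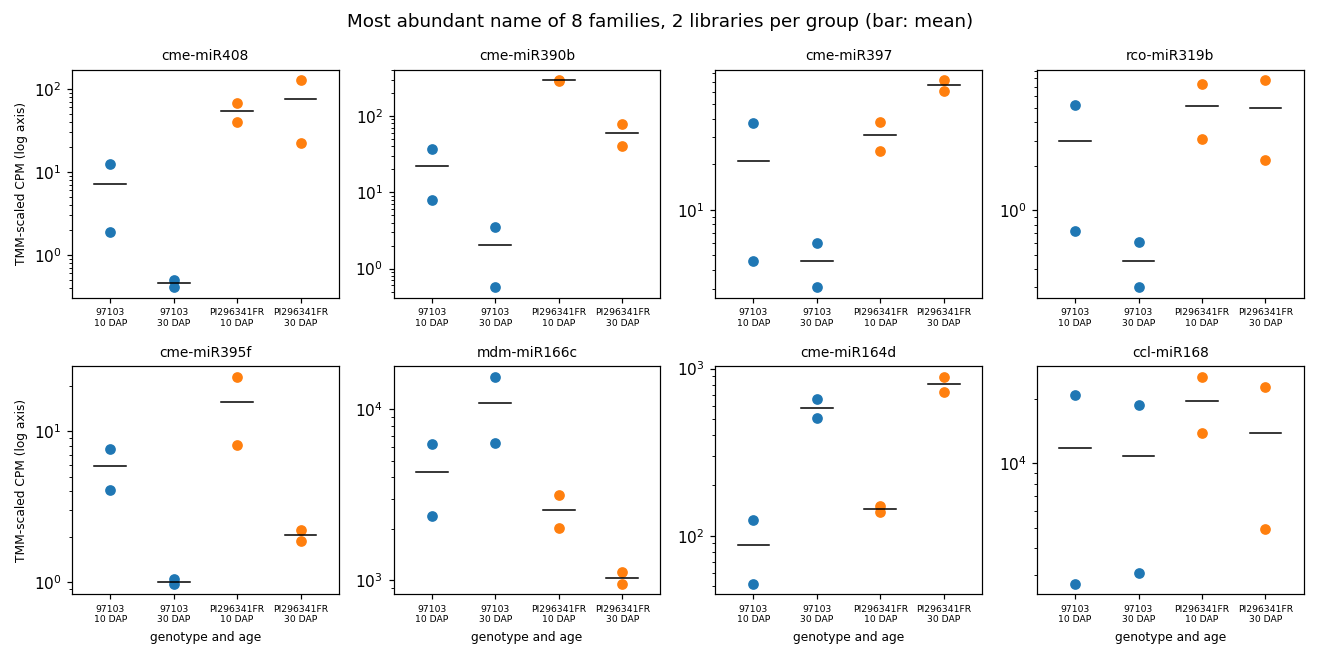
TMM-scaled abundance (CPM, log axis) of the most abundant name of 8 families in the 4 groups of the genotype set, with a point for each of 2 libraries and a bar at the mean. cme-miR408 lies at 0.452 CPM in 97103 at 30 DAP and at 75.2 CPM in PI296341FR, mdm-miR166c at 10908 and 1031 CPM, and ccl-miR168 overlaps between all groups.

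The change with age was asked within each genotype with 30 against 10 DAP. In 97103 all 135 names of miR395, which targets sulphate transporters and ATP sulphurylases, were lower at 30 DAP with a median log2 fold change of -2.48, as were all 46 of miR390 (-4.51), all 20 of miR408 (-4.18) and 37 of 42 of miR319 (-2.62). Many of these names are copies: the 176 tested names of miR395 and miR2111 are 4 profiles. Under RLE factors 29 names of miR390 stayed called, and none of miR395, miR408 or miR319. Single names with large falls were gma-miR160a-3p (-6.59, SE 1.54), vvi-miR2950-5p (-5.97, SE 1.13), cme-miR167e (-5.08, SE 1.11), aqc-miR167 (-4.89, SE 1.10) and the identical bdi-miR390a, osa-miR390-5p, sbi-miR390 and zma-miR390a-5p (-4.53, SE 1.37). The miR164 names had the highest family median, 2.60, and lay 3.31 to 3.40 above the median of all names. cme-miR164d stood at 585 ± 107 CPM at 30 DAP and 87.4 ± 50.9 at 10 DAP (SD, n = 2). 64 of 76 miR164 names were called higher with RLE factors, and none with TMM factors.

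By edgeR's test 243 names were called in 97103, 0 higher and 243 lower, with 365 at an unadjusted p under 0.05, and they make 23 profiles. The split turned with the scaling: 74 higher and 33 lower with RLE factors, 276 and 48 by DESeq2, and 0 and 364 without factors, as the median of all names moved from -0.75 to 0.47 and -1.68. The count also rested on single libraries: it was 91 without replicate 1 of 97103 at 10 DAP, 36 and 66 without replicates 1 and 2 of 97103 at 30 DAP, and 55 and 4 without replicates 1 and 2 of PI296341FR at 30 DAP. With 1 name per profile 1 profile was called. The phosphate and sulphate list and the phloem-mobile list, which share all tested members, had 135 of 176 lower, and 135 adjusted over the list alone (fry, down, adjusted p = 0.0908). Tested as 4 profiles with 1 name each, they had 0 lower and a median of -0.98. The auxin list had 49 lower and 49 adjusted over the list alone (fry adjusted p = 0.161), and the copper list 20 of 40 lower and 20 adjusted over the list alone. The organ growth and meristem list had 38 lower and 0 adjusted over the list alone (fry mixed adjusted p = 0.0296, directional adjusted p = 0.464), the ripening regulator list 1 and 0, and the phase change, MYB regulator and miRNA pathway lists had 0 by edgeR. Without factors 43 names of miR159 and 13 of miR172 were called lower, with 43 lower in the MYB regulator list, 13 in phase change, 18 in ripening regulators, 40 in copper and 79 in organ growth and meristem. The auxin, phosphate and sulphate, and phloem-mobile lists then passed fry, down, each with an adjusted p of 0.0377. With RLE factors no list passed the directional test, 74 organ growth and 64 ripening regulator names were higher, 32 auxin names were lower, and the copper and phosphate and sulphate lists had 0 calls.

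In PI296341FR the same 135 miR395 names were lower at 30 DAP, with a median log2 fold change of -2.93. cme-miR395f stood at 15.5 ± 10.5 CPM at 10 DAP and 2.05 ± 0.235 at 30 DAP (SD, n = 2), from 120 and 30 counts. Relative to the median of all names, miR395 lay at -1.75 to -1.68 over the 3 scalings, against -1.95 to -1.73 in 97103, and of the 3 scalings TMM alone gave these calls. In addition 7 of 201 miR166 names were lower, among them osa-miR166h-3p, sbi-miR166f and zma-miR166m-3p (-3.20, SE 1.08), pab-miR166a (-3.20), dpr-miR166a (-3.18) and vvi-miR166b (-3.11). osa-miR159f had 20 counts at 10 DAP and 3 at 30 DAP, a ratio of 14.3 with an interval of 4.25 to 75.4, and nta-miR2911 fell by 3.11 (SE 1.06), and TMM alone gave these calls too. The miR164 names lay 3.48 to 3.74 above the median of all names and 64 of 76 were called higher with RLE factors.

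By edgeR's test 144 names were called in PI296341FR, 0 higher and 144 lower, with 325 at an unadjusted p under 0.05, and they make 7 profiles. RLE factors gave 65 higher and 0 lower, DESeq2 64 and 0, the stricter filter 62 and 0 and the compared groups alone 104 and 0, while no factors gave 0 calls, with the median of all names at -1.18, -0.51 and -0.37 for TMM, RLE and no factors. Calls numbered 0 without replicate 2 of PI296341FR at 10 DAP, 0 without either PI296341FR library at 30 DAP, and 0 and 65 without replicates 1 and 2 of 97103 at 30 DAP. With 1 name per profile none was called. The phosphate and sulphate list and the phloem-mobile list had 135 lower, and 135 adjusted over the list alone (fry adjusted p = 0.0908). Tested as 4 profiles with 1 name each, they had 0 lower and a median of -0.96. The MYB regulator list had 1 lower and 43 of 45 adjusted over the list alone (fry adjusted p = 0.351), and the organ growth and meristem list 7 and 0. The other lists had 0 calls by edgeR, and 0 adjusted over the list alone.

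Whether the change with age differed between the genotypes was tested as an interaction. cme-miR167e and aqc-miR167, of the family that targets auxin response factors, were the 2 names called. Their difference in the log2 change was 5.90 (SE 1.43) and 5.73 (SE 1.42), with an edgeR adjusted p of 0.0365 for both, as they fell with age in 97103. At an unadjusted p under 0.05 there were 190 names. DESeq2 called 180, all lower, and neither miR167 name was among them: it gave cme-miR167e and aqc-miR167 changes of 6.10 and 5.91, with unadjusted p-values of 0.0213 and 0.0263 and no adjusted p. Without factors 80 were called, all higher, among them all 20 names of miR397, all 20 of miR408 and 36 of miR319. Both miR167 calls were lost without replicate 2 of 97103 or of PI296341FR at 10 DAP, without either 97103 library at 30 DAP, without replicate 1 of PI296341FR at 30 DAP, and with 1 name per profile, and the stricter filter removed both names. In the auxin list 2 were higher adjusted over the list alone and in the copper list 20, and no other list had a call by edgeR.

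The 97103 flesh at 10 and 30 DAP was measured in both sets with no shared library, and 16 names by the same spelling could be compared. The log2 change of cme-miR164c was 3.86 in the stage set, where it was called, and 2.59 in the genotype set, where it was not, and that of cme-miR159a was -0.41 and -2.67, called in neither. cme-miR319a and cme-miR319b stood at 1.17 and 0.56 in the stage set, the first of them called, and at -2.62 and -2.63 in the genotype set, both called with TMM factors and neither with RLE factors. Across the 16 names the log2 fold changes had a Pearson r of 0.743 (permutation p = 0.0011) and a Spearman rho of 0.747 (permutation p = 0.00128), and their covariance was 1.30. The names are not independent, as several belong to a family. The abundance of miR319 names differed widely between the sets, as given above. The sign was the same for 5 of the 16, for 9 without scaling factors and for 10 with RLE factors.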

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

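The test of an offset between the sets was chosen only after the result was seen. cme-miR167e and aqc-miR167 differed between the genotypes in their change from 10 to 30 DAP, by 5.90 and 5.73 on the log2 scale in the interaction test. They fall in separate profiles, with 106 counts each in 97103 at 10 DAP, and 7 and 8 at 30 DAP. At counts this low a difference of few counts can part profiles. As names of the same family with such close counts, they are read as copies of each other rather than as separate results.

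In the comparison of both 97103 sets, an edgeR test of set by age found that the change from 10 to 30 DAP differed for 3 of the 16 names: cme-miR319a by -4.07 (SE 1.12, adjusted p = 0.00735), cme-miR319b by -3.47 (SE 1.12) and cme-miR159a by -2.67 (SE 0.96). This was a joint fit over the 18 shared names, so the scaling factors rest on these names alone. It used 1 dispersion per name for both sets, though their own fits had common dispersions of 0.0323 and 0.422. The SE and adjusted p-values may therefore understate the spread of the genotype set. Changes lay lower in the genotype set for all 16 names, by a median of -2.42. Whether an offset between the scalings of the sets accounts for this cannot be told apart from a difference of single names. Setting that median to 0 left 0 of the 18 names found in both sets differing, against 5 before, but the median comes from the same differences, so the fall in calls is largely fixed by the centring and is no support for an offset. Other libraries, plants or counting rules of the sets were not tested.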

How the results depend on the processing

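The block at 0 and 1 DAP, the crossed block, single libraries left out of the stage set, 1 name per profile, and RLE factors for lists and for the comparison of the sets were chosen after seeing the data. Calls at any age, 30 against 0 DAP and the correlation between the sets kept their side of the threshold under every alternative run, with 125 to 143 calls for 30 against 0 DAP in fits with scaling factors, or 101 when a log2 change of 1 was also required. Without scaling factors cme-miR159a, cme-miR159b and cme-miR162 at 30 against 0 DAP turned to -0.99, -0.56 and -0.84, the medians of the phase change and organ growth lists to -0.46 and -1.26, and both passed the directional fry test. Over both sets 9 tests of a list in a comparison passed the directional fry test without factors, 3 in the stage set and 6 in the genotype set, against 1 with TMM factors, where the mixed test passed in 4. Their construction moves all names by the shift of the median. From 0 to 1 DAP calls went from 0 to 3 by DESeq2 and 37 with the block over those ages, which removes the deviations that replicates of 1 number share. The cause of the other changes was not tested. Without factors calls went from 40 to 70 (10 to 20 DAP) and 93 (20 to 30 DAP). Requiring a log2 change of 1 left 59, 35, 21 and 23 in the steps from 1 DAP on. Leaving out replicates or libraries gave 69 to 113, 23 to 95, 16 to 57 and 20 to 45 there, partly because fewer libraries enter the fit. Leaving out replicate 3 of every age gave 69, 23 and 20 in the steps from 1, 5 and 20 DAP.

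In the genotype set 243 calls for 97103 became 107 with RLE factors, 47 with the stricter filter, 2 with family sums, 1 with 1 name per profile, 74 with the compared groups alone and 4 to 269 with a library left out. The 144 for PI296341FR became 64 by DESeq2, 65 with RLE factors, 0 without factors, 62, 0 and 0 with the stricter filter, family sums and 1 name per profile, and 0 to 170 with a library left out. At 10 DAP the 1 call became 48 by DESeq2, 48 with RLE factors, 50 without factors, 51 with the compared groups alone, 0 with family sums, 0 with 1 name per profile and 0 to 50 with a library left out. At 30 DAP 327 became 603 without factors, 4 with family sums, 39 with 1 name per profile and 199 to 355 with a library left out. The interaction's 2 calls became 180 by DESeq2 (0 of the 2 among them), 80 without factors, 0 with the stricter filter, 0 with family sums, 0 with 1 name per profile and 0 to 2 with a library left out. A library left out leaves a group of 1, assumed to vary like the other groups. Family sums and 1 name per profile test fewer features, at most 35 and 138.

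The replicate block over all 18 stage libraries gave 0 calls from 0 to 1 DAP and changed no other count by over 1.5 times. In the genotype set the titles pair libraries by number alone, and the block gave 292, 144, 53, 343 and 2 calls. Deviations by number had r = 0.57 between 10 and 30 DAP in 97103, so a pairing of these libraries stays open. The value was 0.10 between these ages in PI296341FR and -0.07 between the genotypes at 10 DAP. Deviations of the genotypes at 30 DAP had r = -0.33 by number, and crossed numbers gave 432 calls. Of the named results other than these, 4 without filter, 14 with the stricter filter, 14 without factors, 13 by DESeq2, 12 with RLE factors, 10 with the compared groups alone, 1 with the block and 20 with 1 name per profile lost their call. Calls were gained by 13 without factors, 7 by DESeq2, 7 with the block, 5 with the compared groups alone and 1 with the stricter filter. With a library or replicate left out, calls of named results were lost 194 times and gained 21 times, against 3050 fits of a named result with neither. Depth limits names with few counts, such as hbr-miR6485 at 0 DAP and the miR171 names at 30 DAP, and 2 libraries per group limit the genotype set.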

Other observations

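The count of names by age of highest abundance and the test of the scaling were chosen only after the result was seen. Of the 175 names called at some age, 49 had their highest group mean at 0 DAP, 27 at 1 DAP, 20 at 5 DAP, 18 at 10 DAP, 20 at 20 DAP and 41 at 30 DAP. With RLE factors 56 of 184 were highest at 0 DAP and 50 at 30 DAP. Without factors 63 of 201 were highest at 0 DAP, 48 at 10 DAP and 17 at 30 DAP, so the number of names highest late rests on the scaling.

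cme-miR166b and cme-miR164c had their lowest group mean at 10 DAP. cme-miR166b, which targets class III HD-ZIP transcription factors, stood at 49481 ± 7304 CPM at 0 DAP, 9149 ± 3131 at 10 DAP and 44165 ± 14502 at 30 DAP (SD, n = 3). cme-miR164c stood at 1930 ± 511, 1142 ± 422 and 16539 ± 4548 CPM at these ages. cme-miR156d, of the family that targets SPL transcription factors, fell by 1.72 from 1 to 5 DAP and rose by 1.42 from 10 to 30 DAP (edgeR adjusted p = 0.0107). Its single steps after 5 DAP, of 0.62, 1.08 and 0.34, were not called by edgeR with TMM factors, but the step from 10 to 20 DAP was called by DESeq2 (1.12, adjusted p = 0.0495) and with the replicate block (1.12, adjusted p = 0.0336), and that from 5 to 10 DAP without factors (0.92, adjusted p = 0.0490). In contrast cme-miR2111a had its lowest mean at 0 DAP: it rose by 1.76 from 1 to 5 DAP and by 1.26 from 20 to 30 DAP, the second not called without scaling factors. cme-miR172b fell by 1.26 from 5 to 10 DAP and stood at 484 and 481 CPM at 20 and 30 DAP.

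Other groupings of the libraries were fitted beside the real ones. Of 100 groupings of the 18 stage libraries into 6 groups of 3, the real one included, 1 gave as many calls at any age as the real 175, and the highest other gave 34. A chance labelling of the libraries is therefore unlikely there, though 100 groupings cannot give a share under 1 in 100. The test treats libraries as separate units, so it cannot part age from anything else shared by the libraries of 1 age. For each pair of ages the 6 libraries make 10 splits, too few for a share under 0.05. In the steps from 1, 5, 10 and 20 DAP and for 30 against 0 DAP, 1 of 10 splits reached the real count (109, 79, 40, 40 and 138), and the highest other gave 0, or 1 for 20 to 30 DAP. For 0 and 1 DAP all 10 splits reached the real count of 0, and the highest gave 23. There the numbers pair the libraries: the 4 splits that part all 3 pairs, the real one among them, gave 0 calls at most, and the 6 that part 1 pair reached 23, which points to a difference shared by libraries of 1 number.

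The higher miR319, miR390, miR397 and miR408 names and lower miR165 and miR166 names of PI296341FR at 30 DAP come from libraries that differ widely in total, so depth was tested. After thinning every library to 66572 counts with 1 name per profile, 86.5% of the profiles of these families, 32 of 37, kept their sign and at least 50% of their log2 change. The other 5 were lost to the filter, and calls of these families went from 29 to 21. Thinning keeps the expected share of each name in a library, so most profiles keep their change by construction. A depth effect already in the deposited counts would survive it, so the test cannot decide on depth as the cause. Without each of the 4 libraries at 30 DAP 100% of the 303 called names kept their sign and at least 50% of their size. The lowest share was 0.548, without replicate 2 of 97103. These names were picked as called with all 4 libraries, which favours names whose 2 libraries of a group are alike. The high share is thus partly fixed in advance, and the test cannot decide on a single library as the cause. Scaling also stays open for part of the pattern: RLE factors kept all 303 calls, but without factors 76.6% were kept. All 127 higher names and 105 of 176 lower names were then called, and the sign was kept in all 303. The difference may reflect the genotypes, which was not tested against other plants, and depth cannot be told apart from it. Nor can scaling for the lower names, because the true shift of the median is unknown.

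The deviations of replicate 2 from its group mean correlated across names between 0, 1 and 10 DAP, at r = 0.566 to 0.814. Those at 30 DAP correlated more weakly with them, at 0.255, 0.378 and 0.366. The deviations of replicate 1 also correlated between 0, 1 and 10 DAP, at 0.290 to 0.621. Those of replicate 3 correlated between 0 and 1 DAP (0.661) and between 1 and 30 DAP (0.514) and not between 10 DAP and 0 or 1 DAP (-0.126 and -0.180). Replicate 2 was the library farthest from the others at 0 and 1 DAP, but at 10 DAP that was replicate 1, with a chi-square per degree of freedom of 45.9 and 25.7 against replicates 2 and 3 and 9.17 between these, and since the deviations of a group sum to 0, the correlations of the 3 numbers are not independent and part of the deviation at 10 DAP may come from replicate 1. Names of known families averaged deviations of -0.34, -0.61 and -0.39 on the log2 scale in the replicate 2 libraries of 0, 1 and 10 DAP, and novel_miR names 0.01, 0.03 and -0.06. Flesh of another age in these libraries could give deviations along the change with age of the other groups. The largest correlation with a straight-line slope over the order of ages was r = -0.0888, which argues against a mixture along that line. Changes off the line, such as that of cme-miR166b, lowest at 10 DAP, were not covered. Nor can the slope detect flesh of 1 DAP at 0 DAP or the reverse, as edgeR called 0 names between these ages. Without the 10 most abundant names the lowest correlation was 0.555, so it does not rest on the deviations of these names themselves. Each name weighs the same in r and new factors move all names nearly alike, so this test could hardly fail and decides on no cause. A shared step of handling or library preparation may remain, and no biological explanation was tested.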
